A study of Rattus norvegicus with 15 samples.

How the data were processed

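Small RNA was sequenced from the kidney cortex of PCK rats, a strain with a Pkhd1 mutation that serves as a model of autosomal recessive polycystic kidney disease. From 6 weeks of age the rats ate chow with 0.01%, 0.4% or 4% NaCl for 8 weeks, and there were 15 libraries, 5 per diet. Libraries were made with a TruSeq small RNA kit and read on an Illumina HiSeq instrument, per the labels' protocols. The submitters' processing notes name cutadapt, Bowtie and DESeq. The genome build, the miRNA database and the rule for reads that match several names are not given in the sources used here.

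The authors deposited a table of raw read counts for 600 mature miRNA names, of which 445 are rat names and 155 are names of homologs in other species, and a second sheet that gives each row's name. The homolog names held 13% of all counts. Some names appear to count the same reads more than once. Among the 234 names with a mean of at least 200 reads, 14 pairs kept a log2 ratio with an SD under 0.05 over the libraries. The smaller members of these pairs held 12.6% of all counts. Such pairs are said below to share reads, on the steady ratio alone, as reads and sequences were not inspected. miR-22-3p and bta-miR-3600 are such a pair, as are miR-199a-3p and bta-miR-3604, and miR-125b-5p and miR-3588. The values of both names of a pair are therefore uncertain as separate miRNAs. The authors also deposited tables of their own comparisons, with log2 fold changes and p-values per file headers, from DESeq, DESeq2 and edgeR. These are cited only where named as the authors' deposited table. The 90 columns of per-sample counts inside those tables were not used.

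Samples were grouped by the diet in the labels. The labels number no replicates, so replicate numbers only name libraries and pair nothing. The labels' protocol speaks of pools of 2 to 3 rats with 2 pools per condition, which differs from the 5 samples listed per diet. Within diets every pair of libraries differed by far more than counting error, so none was taken for a copy of another and each was counted singly. Separate libraries of 1 pool would differ as well, so libraries of a diet that share a pool are not excluded. As the labels do not tie libraries to animals or pools, p-values measure the spread between these samples, which may be technical.

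Counts were analysed with edgeR 4.0.16 in R 4.3.3. filterByExpr kept 519 names and left out 81. TMM factors, robust dispersions and 1 quasi-likelihood fit with 3 diet means (12 residual degrees of freedom) gave 3 pairwise contrasts and a joint test of any diet difference, and a slope over the diet order gave a trend. Names with a Benjamini-Hochberg adjusted p under 0.05 were called. Scaled CPM are CPM relative to the TMM-scaled library size, and values are given as mean ± SD over 5 libraries. The deposited counts were also tested with DESeq2 1.42.0 and limma-voom (limma 3.58.1).

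Before the data were examined, 19 miRNA lists were fixed. They were kidney-enriched epithelial, miR-30 family, miR-200 family, let-7 family, miR-29 family, kidney injury and fibrosis, cystic kidney disease, miR-17 family and clusters, sodium transport and renin-aldosterone, immune cells, endothelium, smooth muscle and fibroblasts, striated muscle, red blood cells, neural and endocrine, liver, hypoxia, p53 and senescence, and the Dlk1-Dio3 imprinted cluster. The 17 lists with at least 3 tested members entered camera on log2 CPM (prior count 2) with a preset correlation of 0.01, camera with an estimated correlation, and fry, in its directional form unless said to be mixed, with adjustment over 51 tests for each. An exact two-sided permutation test of each list's mean log2 CPM over the 126 splits of 10 libraries was added after the data were seen.

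The naming rule was fixed at the same time. For each pairwise comparison it takes the 13 largest increases and 12 largest decreases among the called names (all if 25 or fewer), the 10 smallest p where fewer than 5 pass, up to 4 members of each list, and always miR-9a-5p, miR-21-5p, miR-192-5p, miR-10b-5p and the 5 most abundant names. List members that the rule takes for abundance and that passed no test are given here as counts and medians of their list, without names. That narrowing was decided after the values were seen, because 152 values that did not pass, those named later included, changed sign in 145 of 1924 refits and in 66 leave-one-out extremes, and these have no direction to report. A few further names were added after their values were seen and are said to be so.

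Alternatives fixed before the data were examined were DESeq2 size factors, upper-quartile factors, library totals only, no filter, a filter at a mean of 10 CPM, DESeq2, limma-voom, the 5 most abundant names left out, no robust estimation, only the 2 diets compared, log10 of the NaCl percentage for the trend, and each library left out in turn. Counting pools once was not run, because the labels do not say which libraries share a pool and no libraries matched within counting error. Alternatives chosen after seeing the data were rat names only, names that share reads counted once, and the library of each diet richest in other-species names left out. Richest here means the highest upper decile of the deviation of these names from their diet mean, not the largest share of reads. The test per name was checked on simulated counts for the 519 names, with 200 changed per run in 5 runs. The list tests were checked in 20 further runs with the kidney injury and fibrosis list moved 1.5-fold on 0.01% NaCl. Camera and fry called 40 of 40 tests of that list in the low-salt comparisons. In 340 tests of 4% minus 0.4% NaCl, where nothing was moved, camera called 4 with the preset correlation. It called 1 with an estimated correlation, and fry called 3. Each miRNA was drawn independently in these runs, so they do not show how the list tests behave when list members vary together. For 0.01% minus 0.4% NaCl the fit recovered 40.6% of 1.5-fold, 77.3% of 2-fold and 91.3% of 3-fold changes, and 4.34% of its calls were false. Those 5 runs gave 714 calls together, where the data gave 87. With more changed names the adjusted threshold is looser, so the recovered shares may be too high for the data. The names were drawn independently there too. Library totals ran from 4.17 to 7.83 M reads, and the median standard error of a log2 fold change was 0.23. Gene neighbours came from the RefSeq table of the rat assembly GRCr8, used only for names and for which genes lie near each other, and 370 of 397 tested rat names matched 1 gene.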

Results

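The study asked how the salt content of the diet alters miRNA abundance in the cystic kidney of PCK rats. Mature miRNAs were counted in 5 cortex libraries from rats fed 0.01% NaCl, 5 from rats fed 0.4% NaCl and 5 from rats fed 4% NaCl. Libraries held 6.55 ± 0.769 M reads (mean ± SD, n = 5) on 0.01% NaCl, 5.78 ± 1.0 M reads on 0.4% and 4.91 ± 0.54 M reads on 4%. The most abundant name was miR-10a-5p, with 31.6 ± 5.84% of reads on 0.01% NaCl, 24.6 ± 5.45% on 0.4% and 24.9 ± 0.871% on 4%. It was followed by miR-22-3p, its read-sharing partner bta-miR-3600, miR-30a-5p and miR-192-5p.

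On the salt-deficient diet (0.01% NaCl), 40 of 519 tested miRNA names were higher and 47 lower than on 0.4% NaCl. The largest increase among the called names was in miR-205, an epithelial miRNA, from 27.4 ± 9.87 to 96.5 ± 50.9 scaled CPM (n = 5 each), and the largest decrease was in miR-592, from 6.11 ± 2.57 to 0.793 ± 0.366. miR-9a-5p, best known from neural tissue, rose from 188 ± 71.1 to 445 ± 116. miR-21-5p, which accumulates in injured and fibrotic kidney, rose from 25810 ± 6029 to 46000 ± 9737. Of the 12 largest decreases among the called names, 8 are in the list of the Dlk1-Dio3 imprinted cluster, a maternally expressed group of miRNA genes.

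In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold changes were 1.81 ± 0.40 (SE) for miR-205 (adjusted p = 0.00558), -2.93 ± 0.40 for miR-592 (adjusted p = 0.000832), 1.25 ± 0.27 for miR-9a-5p (adjusted p = 0.00513) and 0.83 ± 0.26 for miR-21-5p (adjusted p = 0.0362). All 5 low-salt libraries lay beyond all 5 of the 0.4% diet for miR-592 and miR-21-5p, and 4 of 5 did for miR-205 and miR-9a-5p. The 2 sets of libraries did not overlap for 75 names (14.5%), where chance gives 0.794%. The other large increases were in miR-20b-5p (log2 fold change 1.54), miR-224-5p (1.43), mmu-miR-1983 (1.39), hsa-miR-4454 (1.32), miR-187-3p (1.29), miR-9b-3p (1.26), miR-503-5p (1.23) and miR-879-5p (1.21). Outside the Dlk1-Dio3 list, large decreases were found in miR-203a-5p (-1.65), dps-miR-1002-3p (-1.64) and miR-409b (-1.56), whose gene lies within the span of that list on GRCr8. miR-10a-5p (0.54 ± 0.20), miR-192-5p (-0.45 ± 0.18), miR-10b-5p (0.35 ± 0.19), miR-30a-5p (0.23 ± 0.12), miR-22-3p (-0.068 ± 0.10) and bta-miR-3600 (-0.067 ± 0.10) did not pass the test.

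**Figure D1:**
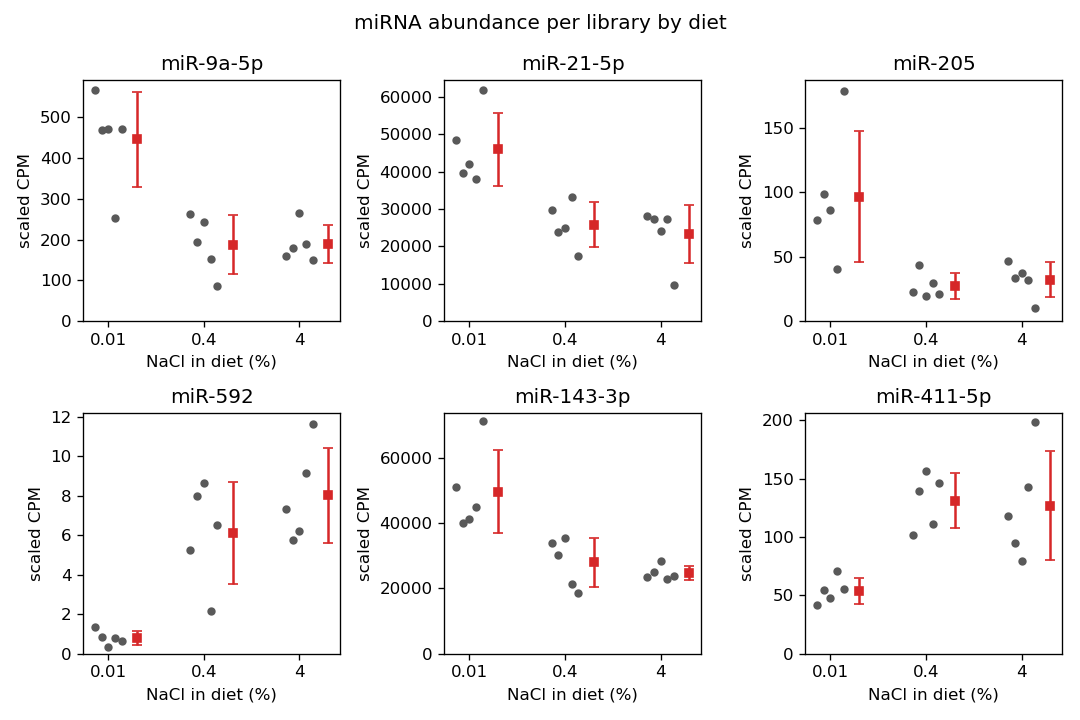
Scaled CPM (vertical axes, from 0) of 6 miRNAs against the NaCl percentage of the diet, with grey points for the 5 libraries of each diet and red squares with bars for their mean and SD. miR-592 averaged 0.793 on 0.01% NaCl against 6.11 on 0.4% and 8.02 on 4%, while miR-9a-5p averaged 445 against 188 and 189.

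Of the 32 tested members of the Dlk1-Dio3 list, 25 fell on 0.01% NaCl, none rose and 7 did not pass, and 29 fell when p was adjusted over the list alone. Values were negative for 30 members and positive for 2, and the genes of those 2 lie within 10 kb of each other. The list's median log2 fold change was -1.42. miR-377-3p (-2.28), miR-494-3p (-2.15), miR-376a-5p (-2.12), miR-376b-3p (-1.92), miR-485-5p (-1.89), miR-154-5p (-1.68), miR-376c-3p (-1.66) and miR-369-5p (-1.58) were among those that fell, as were miR-541-5p (-1.40), miR-411-5p (-1.28) and miR-381-3p (-1.53). Camera with a preset correlation gave an adjusted p of 3.59e-15 and fry 0.0129. With an estimated correlation camera gave an unadjusted p of 0.0266 and an adjusted p of 0.79. Adjustment gave several lists this same value, the smallest that any list reached. The list's mean log2 CPM was 1.63 ± 0.179 on 0.01% NaCl and 2.76 ± 0.42 on 0.4% (n = 5 each), a difference that no other split of the 10 libraries reached (exact permutation test, p = 0.00794, the smallest possible, and adjusted p = 0.0578 over 51 tests). The miR-200, kidney injury and fibrosis, smooth muscle and fibroblast, and p53 lists gave the same p and adjusted p in this comparison. That test therefore does not set the Dlk1-Dio3 list apart from them. Many members were scarce, with a median of 20 reads per library, and library 5 of the 0.4% diet was the highest of its diet for miR-154-5p, miR-376b-3p, miR-377-3p and miR-494-3p.

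**Figure D2:**
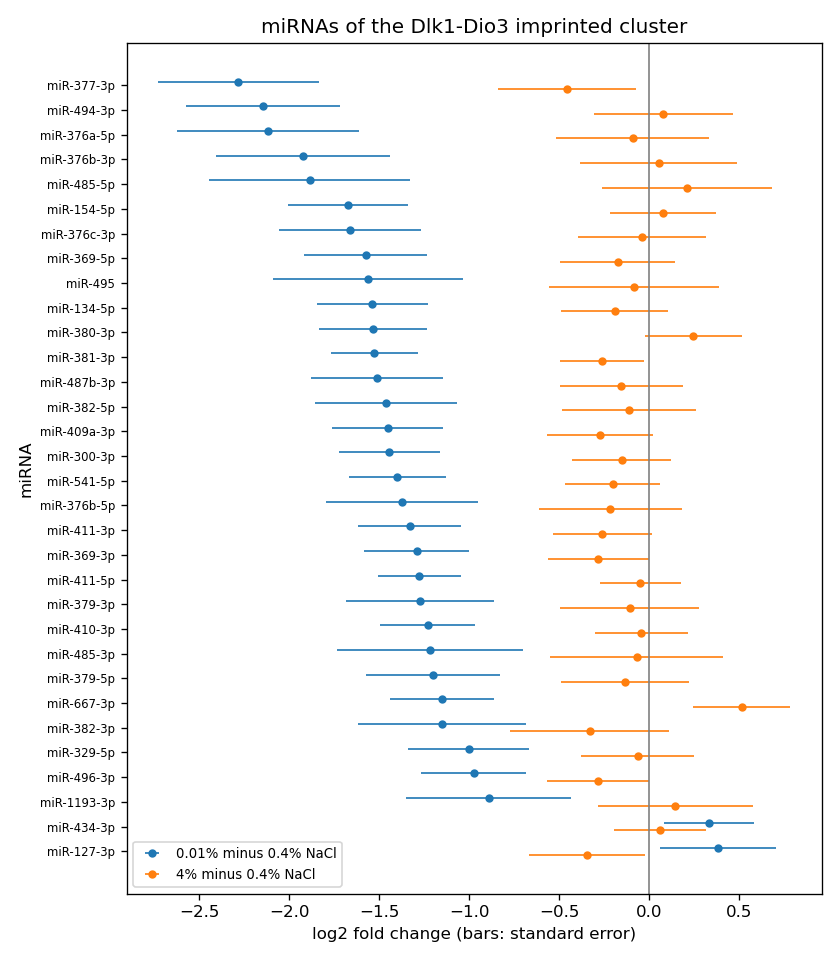
Log2 fold change (horizontal axis) of the 32 tested Dlk1-Dio3 miRNAs, blue for 0.01% minus 0.4% NaCl and orange for 4% minus 0.4% NaCl, with bars for the standard error. The medians were -1.42 and -0.109, and 25 members passed the test in the first comparison and 0 in the second.

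In the miR-200 family, which maintains epithelial identity, 3 of 8 tested members rose: miR-141-5p (log2 fold change 1.23), miR-200c-3p (1.17) and miR-141-3p (1.04). The miR-141 and miR-200c genes lie within 10 kb of each other, so the list tests may follow 1 locus and not the family. miR-200a-3p (0.088 ± 0.10), miR-200b-3p (0.036 ± 0.093) and miR-429 (0.16 ± 0.11), named after their values were seen, did not pass. The family's median was 0.125, and -0.0485 with library totals only. Fry gave an adjusted p of 0.036, which 5 of 15 refits without 1 library kept, and camera gave 0.0721 (adjusted p = 0.79 with an estimated correlation), which passed in 2 of 15 refits. Fry gave 0.192 with library totals only and 0.073 without the 3 libraries richest in names from other species, an alternative chosen after seeing the data.

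In the smooth muscle and fibroblast list, 5 of 8 members rose and none fell, with a median of 0.637. They were miR-143-3p (0.83 ± 0.18), miR-145-3p (0.58 ± 0.18), miR-199a-5p (0.71 ± 0.23), miR-199a-3p (0.64 ± 0.18) and bta-miR-3604 (0.67 ± 0.18), the last of which shares its reads with miR-199a-3p. Fry gave an adjusted p of 0.036, which 4 of 15 refits without 1 library kept and which was 0.0725 with library totals only, and camera gave 0.00266 (adjusted p = 0.79 with an estimated correlation). In the kidney injury and fibrosis list, 4 of 20 members rose and 1 fell (11 and 2 adjusted over the list alone), with miR-31a-5p (1.06) and miR-21-5p among the increases and miR-382-5p (-1.46), also a Dlk1-Dio3 miRNA, as the decrease. In the cystic kidney disease list, 3 of 15 rose (4 adjusted over the list alone), and 6 of its members are also in the injury list. In the miR-17 family and clusters, 2 of 17 rose (1 adjusted over the list alone), miR-20b-5p and miR-92b-3p (0.68). In the p53 and senescence list, 1 of 6 rose, miR-34b-3p (0.95), and 4 adjusted over the list alone. Most members of the p53 list are arms of the neighbouring miR-34b and miR-34c genes, so it too may follow 1 locus. Camera adjusted p were 0.0111, 0.0111, 0.0334 and 0.0227 for these 4 lists (adjusted p = 0.79 for each with an estimated correlation), and fry called none of them. Without the 3 libraries richest in names from other species, fry called the kidney injury list (adjusted p = 0.0041) and the p53 list (adjusted p = 0.00865), and it called both without library 5 of the 4% diet as well. The camera call of the cystic list was lost without library 5 of the 0.4% diet (adjusted p = 0.0769), and that of the miR-17 list without that library (adjusted p = 0.126) or library 1 or 5 of the 0.01% diet.

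In the list fixed as kidney-enriched epithelial, 3 of 15 fell and none rose: miR-203b-3p (-1.42), miR-203a-3p (-0.80) and miR-194-5p (-0.60). The miR-203a and miR-203b genes lie within 10 kb of each other, so their falls may not be separate. In the sodium transport and renin-aldosterone list, 1 of 21 rose, miR-9a-5p, and 2 fell, miR-335 (-1.38) and miR-194-5p, while adjusted over the list alone 4 rose and 2 fell. The study names miR-9a-5p itself, so its place in that list and in the neural and endocrine list (1 of 9 rose) is not independent evidence. In the miR-29 family 1 of 6 fell, miR-29c-3p (-0.56). In the immune cell list 2 of 13 rose, miR-147 (0.85) and miR-21-5p. No member passed among 11 of the miR-30 family, 9 of the let-7 family, 4 of the endothelial list, 3 of the striated muscle list, 3 of the red blood cell list and 2 of the hypoxia list, and the liver list had no tested member. Camera and fry called none of the lists of this paragraph with all libraries and TMM scaling. Without the 3 libraries richest in names from other species both called the immune cell list (adjusted p = 0.00414 and 0.00145), as both did without library 5 of the 4% diet, and camera alone did without library 4 of the 0.4% diet. With library totals only, camera called the immune cell list (adjusted p = 0.0443; in the unaltered fit adjusted p = 0.915 with an estimated correlation) and fry the kidney-enriched (adjusted p = 0.00408) and striated muscle (adjusted p = 0.00599) lists. Fry's mixed test, which asks for change in either direction, called the kidney-enriched (adjusted p = 0.000511), sodium transport (adjusted p = 0.00266), miR-17 (adjusted p = 0.0471), miR-200 (adjusted p = 0.0203) and Dlk1-Dio3 (adjusted p = 0.00124) lists. For red blood cells the median was -0.0453 where camera's direction was up.

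The count of 87 was 55 with a filter at a mean of 10 CPM, and 54 of those were shared. Without the library of each diet richest in names from other species, an alternative chosen after seeing the data, 59 were higher and 49 lower, and 78 of the 87 were among them. With library totals only, the median of all names shifted by -0.184 and the calls were 25 higher and 79 lower, so the balance of increases and decreases depends on the scaling. miR-21-5p kept its call in 8 of 15 refits without 1 library, with log2 fold changes from 0.69 to 0.92 and a largest adjusted p of 0.1. It lost the call without library 1, 3 or 5 of the 0.01% diet, 2, 3 or 5 of the 0.4% diet, or 3 of the 4% diet. The corresponding numbers of refits were 4 for miR-92b-3p, 6 for miR-199a-5p, 7 for dps-miR-1002-3p, 8 for miR-145-3p, 10 for miR-147, 11 for miR-485-5p, 13 for miR-199a-3p, and 14 for bta-miR-3604 and miR-382-5p.

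Between the high-salt diet (4% NaCl) and 0.4% NaCl no miRNA passed the threshold. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 519, DESeq2 and limma-voom called 0, and 27 had an unadjusted p under 0.05 where 26 are expected by chance. The log2 fold changes were 0.010 ± 0.27 for miR-9a-5p, -0.15 ± 0.25 for miR-21-5p, -0.25 ± 0.18 for miR-192-5p, -0.065 ± 0.20 for miR-10a-5p, -0.075 ± 0.19 for miR-10b-5p, -0.14 ± 0.12 for miR-30a-5p, -0.076 ± 0.10 for miR-22-3p and -0.076 ± 0.10 for bta-miR-3600.

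None of the 10 names with the smallest p passed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.449 for each). Values were positive for the lymphocyte miRNA miR-150-5p (0.97 ± 0.32), hsa-miR-1273g-3p (1.51 ± 0.50), mmu-miR-5099 (1.00 ± 0.32), mmu-miR-6239 (0.91 ± 0.32), mmu-miR-1195 (0.51 ± 0.17), miR-3588 (0.29 ± 0.096) and miR-125b-5p (0.27 ± 0.089), the last 2 of which share reads. They were negative for miR-760-3p (-1.03 ± 0.30), the muscle miRNA miR-208b-3p (-0.80 ± 0.22) and the erythroid miRNA hsa-miR-486-5p (-0.64 ± 0.22). No list was called by camera or fry with all libraries and TMM scaling, and no member of any list passed over all names. Camera called the red blood cell list with library totals only (adjusted p = 0.0426) and without library 3 of the 0.01% diet, 2, 3 or 5 of the 0.4% diet, or 3 of the 4% diet. Without library 5 of the 4% diet it called the kidney-enriched, miR-30, injury, immune cell, smooth muscle, p53 and Dlk1-Dio3 lists, and fry the immune cell list. Without library 1 of the 0.4% diet camera called the miR-30, let-7 and Dlk1-Dio3 lists, and without library 4 of that diet the kidney-enriched and immune cell lists. These camera calls are at the preset correlation, and with all libraries adjusted p was 0.79 for the red blood cell and miR-30 lists and at least 0.938 for the others with an estimated correlation, which was not run without single libraries. Adjusted over the list alone, 1 of 3 red blood cell miRNAs and 1 of 3 striated muscle miRNAs fell. List medians ran from -0.799 for red blood cells to 0.27 for immune cells. For the p53, immune cell, kidney-enriched, injury and Dlk1-Dio3 lists, leaving out the 3 libraries richest in other-species names, chosen after seeing the data, gave camera adjusted p of 0.0154, 1.41e-05, 0.00414, 0.0133 and 0.000251 at the preset correlation (with all libraries, adjusted p of at least 0.938 for each with an estimated correlation), and of all lists fry then called the immune cell list alone (adjusted p = 0.0041). The median and camera's direction differed in sign for the miR-17, sodium transport, endothelial and striated muscle lists.

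For 79 of the 87 names called between 0.01% and 0.4% NaCl, the 95% interval of the 4% minus 0.4% change excluded the low-salt value. Their median absolute log2 fold change was 1.17 on the low-salt diet and 0.179 on the high-salt diet, where the median half-width of the interval was 0.528. These names were chosen for their low-salt change, which by itself makes the first median the larger and such an exclusion more likely. The intervals are not adjusted for the number of names. The adjusted test of 0.01% minus 4% NaCl called 66 of the 87. For 63 of the 87 the 2 changes had the same sign. Both changes subtract the same 0.4% libraries, which by itself favours the same sign. In simulations with no effect their correlation across names was 0.496. The shared sign therefore does not show an effect of the high-salt diet.

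On 0.01% NaCl, 38 of 519 names were higher and 68 lower than on 4% NaCl. miR-592 was lower (0.793 ± 0.366 against 8.02 ± 2.42 scaled CPM), and miR-205 (96.5 ± 50.9 against 32.1 ± 13.6), miR-9a-5p (445 ± 116 against 189 ± 45.5), miR-21-5p (46000 ± 9737 against 23290 ± 7777) and miR-143-3p, a smooth muscle miRNA (49600 ± 12810 against 24660 ± 2186), were higher. In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment their log2 fold changes were -3.32 ± 0.40 (adjusted p = 8.68e-05), 1.59 ± 0.40 (0.013), 1.24 ± 0.27 (0.00692), 0.98 ± 0.26 (0.0158) and 1.01 ± 0.18 (0.00281).

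Other large increases were in hsa-miR-4454 (1.32), miR-9b-3p (1.19), miR-21-3p (1.15), mmu-miR-676-5p (1.11), miR-542-3p (1.11), miR-200c-3p (1.06), miR-141-5p (1.02), miR-224-5p (0.96) and miR-141-3p (0.85). Large decreases were in bta-miR-1940 (-2.18), hsa-miR-1273g-3p (-2.13) and miR-184 (-2.11). The called decreases of miR-219a-2-3p and hco-miR-5941 rested on few reads. miR-219a-2-3p had 1 read over the 5 low-salt libraries and 52 over the 5 high-salt ones, a ratio of 0.0144 (exact 95% interval 0.000358 to 0.084, counting error only), and the fitted log2 fold change of -5.17 is no bound. For hco-miR-5941, with 6 reads over the low-salt libraries, the ratio was 0.0425 (0.0152 to 0.0955). Among the 5 most abundant names, miR-10a-5p (0.61 ± 0.20) and miR-30a-5p (0.37 ± 0.12) rose, and miR-192-5p (-0.20 ± 0.18), miR-22-3p (0.0076 ± 0.10) and bta-miR-3600 (0.0092 ± 0.10) did not pass, nor did the scarcer miR-10b-5p (0.42 ± 0.19).

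Of the 32 Dlk1-Dio3 miRNAs, 21 fell and none rose (29 fell and 1 rose adjusted over the list alone), with a median of -1.25. miR-494-3p (-2.23), miR-485-5p (-2.10), miR-376a-5p (-2.03), miR-376b-3p (-1.98), miR-377-3p (-1.83), miR-380-3p (-1.78), miR-667-3p (-1.67), miR-381-3p (-1.27) and miR-411-5p (-1.23) were among them. Camera gave an adjusted p of 1.6e-12 (adjusted p = 0.79 with an estimated correlation) and fry 0.0129, or 0.0593 without library 4 of the 4% diet. In the miR-200 family 3 of 8 rose, again those of the neighbouring miR-141 and miR-200c genes. The family had a fry adjusted p of 0.036 that 5 of 15 refits kept and a camera adjusted p of 0.0512 (adjusted p = 0.79 with an estimated correlation), which passed in 8 of 15 refits. The family's median was 0.154, and -0.0772 with library totals only, where fry gave 0.589, and fry gave 0.073 without the 3 libraries richest in names from other species. In the smooth muscle and fibroblast list 2 of 8 rose, miR-143-3p and miR-145-3p (0.60), with a camera adjusted p of 0.0111 (adjusted p = 0.79 with an estimated correlation) and a fry adjusted p of 0.107.

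In the kidney injury and fibrosis list 3 of 20 rose, including miR-31a-5p (0.75), and 1 fell, miR-382-5p (-1.35). In the cystic kidney disease list 4 of 15 rose, including miR-25-3p (0.37). In the miR-17 family and clusters 1 of 17 rose, miR-25-3p, and 1 fell, miR-93-3p (-0.73). Camera gave adjusted p of 0.00822, 0.0111 and 0.0379 for these lists (adjusted p = 0.79 for each with an estimated correlation), and fry called none. The camera call of the miR-17 list was lost without the 3 libraries richest in names from other species (adjusted p = 0.066), and without library 1 or 5 of the 0.01% diet or 4 or 5 of the 4% diet (largest adjusted p = 0.095). In the kidney-enriched epithelial list 2 of 15 rose and 4 fell, with miR-203b-3p (-1.15), miR-203a-3p (-0.68) and miR-194-5p (-0.50) among the decreases. miR-335 (-0.99) and miR-194-5p fell and miR-9a-5p rose among 21 of the sodium transport list. In the immune cell list miR-150-5p (-1.11) and miR-342-3p (-0.75) fell and miR-21-5p rose among 13. miR-29c-3p (-0.57) fell in the miR-29 family, miR-499-5p (-0.73) in the striated muscle list, and miR-30a-5p rose in the miR-30 family. No member passed in the let-7, endothelial, red blood cell, hypoxia and p53 lists, and camera called none of the lists named after the miR-17 family and clusters. Camera called the p53 list with library totals only (adjusted p = 0.0196) and in 6 of 15 refits without 1 library (in the unaltered fit adjusted p = 0.79 with an estimated correlation), and with library totals only fry called the kidney-enriched (adjusted p = 0.00408) and endothelial (adjusted p = 0.0348) lists. Fry's mixed test called the kidney-enriched (adjusted p = 0.000771), sodium transport (adjusted p = 0.0203), immune cell (adjusted p = 0.033), miR-200 (adjusted p = 0.0471) and Dlk1-Dio3 (adjusted p = 0.00133) lists. For the let-7 family the median was -0.032 and camera's direction was up. For the neural and endocrine list (1 of 9 rose, miR-9a-5p) the median was -0.105 and camera's direction was up.

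With library totals only, the median of all names shifted by -0.239 and the calls became 14 higher and 117 lower. Without the library of each diet richest in other-species names, 31 were higher and 44 lower, and 63 were shared. Calls that did not hold in all 15 refits without 1 library were those of miR-10a-5p (5 refits kept it, lowest log2 fold change 0.41), miR-30a-5p (6), miR-219a-2-3p (6), miR-203a-3p (7), miR-224-5p (9), miR-145-3p, miR-382-5p and hco-miR-5941 (10 each), miR-25-3p and miR-499-5p (11 each), miR-150-5p (12), miR-31a-5p, miR-93-3p and miR-9b-3p (13 each) and miR-194-5p (14).

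The 2 low-salt comparisons shared 66 calls, 27 higher in both and 39 lower in both, where independent lists would share 2.93 and 6.16. Both comparisons use the same low-salt libraries. In 50 simulations with no effect the overlap was 0, which follows from the near absence of calls there and does not measure what the shared libraries add to 66. The simulated correlation of log2 fold changes across names, which are not independent replicates, was 0.506 against 0.878 observed. The covariance was 0.321 observed and 0.0595 simulated, a difference of 0.261. With the low-salt libraries divided between the comparisons, over 10 divisions, the median overlap was 3 higher and 9 lower (0.168 and 0.951 if independent), with a correlation of 0.655 and a covariance of 0.271. For the low-salt and high-salt changes against the same 0.4% libraries the covariance was 0.0278 against 0.0581 simulated, a difference of -0.0303, and the correlation was 0.157 against 0.496 simulated. With the 0.4% libraries divided, the covariance was -0.0286 and the correlation -0.111.

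The joint edgeR quasi-likelihood test of any diet difference called 85 names. The trend over the diet order called 81, of which 52 had a positive slope and 29 a negative one. A step between 0.01% NaCl and the other diets gives such a slope too, and 4% minus 0.4% NaCl had 0 calls. The trend therefore does not show a graded response. With DESeq2 size factors the trend's split was 38 higher and 40 lower, and with library totals only it was 99 and 13. The number with a trend was 18 without the 3 libraries richest in other-species names, and it was 17, 31, 29 and 28 without library 1, 2, 3 or 5 of the 0.01% diet and 32 without library 5 of the 4% diet.

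In the authors' deposited tables, the numbers of names with an adjusted p under 0.05 between 0.01% and 0.4% NaCl were 51 with DESeq, 102 with DESeq2 and 94 with edgeR. Between 0.01% and 4% the authors' deposited tables had 64 with DESeq, 108 with edgeR, and 60 higher and 74 lower with DESeq2, and between 4% and 0.4% they had 0 with each tool.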

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

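No test in this part was chosen after its result was seen, except that the permutation test of a diet effect was made exact after a sampled run. Among the sets of 5 libraries of a diet (named miRNAs and total reads), 16 held a library whose gap to the nearest other exceeded what Dixon's test allows, where chance gives about 1 in 20 sets, or 11.1. On 4% NaCl, library 5 was lowest for miR-21-5p (9655 scaled CPM against 24130 to 28200), and highest for miR-192-5p (74510 against 41130 to 49810) and hsa-miR-486-5p (498 against 302 to 345). Library 3 of that diet was highest for dps-miR-1002-3p (5.83 against 2.81 to 3.15) and miR-9b-3p (54.7 against 28 to 33.5). On 0.4% NaCl, library 5 was highest for the Dlk1-Dio3 miRNAs miR-154-5p (3.74 against 1.81 to 2.01), miR-376b-3p (9.59 against 2.27 to 4.17), miR-377-3p (3.9 against 1.81 to 2.21) and miR-494-3p (17.4 against 3.26 to 5.82), and lowest for miR-187-3p (11.5 against 17.7 to 20.1). Library 4 of that diet was highest for mmu-miR-5099 (14 against 5.87 to 7.03). On 0.01% NaCl, library 5 was highest for miR-503-5p (11.9 against 4.96 to 6.51), mmu-miR-676-5p (5.07 against 2.63 to 3.25) and miR-219a-2-3p (0.164, a single read, against 0), library 4 for miR-203a-5p (16 against 5.99 to 8.51) and library 1 for miR-376b-3p (1.91 against 0.861 to 1.17).

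In each diet 1 library was rich in a part of the names from other species. The upper decile of the deviation of 117 such names from their diet mean was 2.37 (log2) in library 2 on 0.01% NaCl, 1.73 in library 4 on 0.4% and 1.45 in library 5 on 4%, against at most 0.825 in the other libraries. None of these 3 held the largest share of reads in homolog names in its diet. The shares were 13.2% against 13.5% in library 4 on 0.01% NaCl, and 15.5% against 15.8% in library 5 on 0.4%. On 4% NaCl the share was 14% against 14.3% in library 2, and the median deviation was 0.0345 against 0.192 in library 1. Low depth was tested as a cause, and 2 of these 3 libraries did not have the smallest total of their diet. A diet effect on the upper decile was tested as well. The largest difference between diet means of a like index was 0.317 of its SD within diets (exact permutation test over 756756 assignments, p = 0.833). That test does not bear on why 1 library stands out within a diet. A diet difference in the median of the same names was not tested. From their mean over all libraries it ran from -0.318 to 0.0909 (log2) on 0.01% NaCl, -0.111 to 0.234 on 0.4% and -0.0907 to 0.32 on 4%. No biological explanation within a diet was tested, and RNA from another source stays open.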

How the results depend on the processing

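The alternatives with rat names only, with shared reads counted once and without 3 libraries, and the narrowing of the names, were chosen after seeing the data. No called value named in the text, of 98, changed sign in 1215 refits, 49 of which lost the call, and 25 of the 98 values lost it without at least 1 library. The refits reuse the libraries in which these values were called, so a kept sign was likely beforehand. The 0 calls between 4% and 0.4% NaCl held in every alternative and without each library in turn. Without 1 library, calls ran from 69 to 107 between 0.01% and 0.4% NaCl, from 74 to 123 between 0.01% and 4%, from 71 to 102 for any diet difference, from 17 to 111 for the trend, and from 9 to 19 for list tests by camera (main 11, 19 without library 5 of the 4% diet). A mean of at least 10 CPM left 55 calls between 0.01% and 0.4%, with fewer names tested. DESeq2 called 1.3e+02 (rounded to 2 digits) for any diet difference against 85. The trend had 18 calls without the 3 libraries richest in other-species names, an alternative chosen after seeing the data. An estimated correlation called 0 lists. Sign changes occurred in 32 refits or leave-one-out extremes of values that did not pass. Between 4% and 0.4%, library totals only gave 0.021 for miR-10a-5p and 0.0015 for miR-10b-5p, and miR-21-5p was 0.18 without the 3 libraries. miR-9a-5p was -0.013 with DESeq2 size factors, -0.013 in DESeq2, -0.0071 without the 5 most abundant names, -0.014 with shared reads counted once and -0.0054 with only the 2 diets. Between 0.01% and 4%, bta-miR-3600 and miR-22-3p were -0.21 and -0.22 with totals only, -0.045 and -0.046 with upper-quartile factors, -0.0044 and -0.0059 in limma-voom, and -0.021 and -0.022 without the 3 libraries. miR-22-3p was -0.019 with rat names only, and miR-192-5p was 0.014 without the 3 libraries. Between 0.01% and 0.4%, totals only gave -0.090 for miR-200a-3p, -0.14 for miR-200b-3p and -0.0069 for miR-429, and miR-200b-3p was -0.010 with upper-quartile factors and -0.021 without the 3 libraries. Leave-one-out ranges between 0.01% and 0.4% were -0.14 to 0.0048 for bta-miR-3600, -0.14 to 0.0039 for miR-22-3p and -0.045 to 0.083 for miR-200b-3p. Between 4% and 0.4% they were -0.16 to 0.057 for miR-10a-5p, -0.17 to 0.064 for miR-10b-5p, -0.25 to 0.036 for miR-21-5p and -0.16 to 0.17 for miR-9a-5p. Between 0.01% and 4% they were -0.075 to 0.071 for bta-miR-3600 and -0.077 to 0.069 for miR-22-3p. The cause was not tested. Depth limits the scarce Dlk1-Dio3 miRNAs, with a median of 20 reads per library.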

Other observations

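Among the tests here, the one on stromal cells, the chi-square version of the pair test, the control pairs, the subset of abundant members and thinning without replacement in place of with replacement were chosen after the results they bear on were seen. Mature miRNAs of several neighbouring genes changed in the same direction on 0.01% against 0.4% NaCl, and these names were chosen after their values were seen. miR-322-5p (log2 fold change 0.79 ± 0.17), miR-351-5p (0.75 ± 0.18), miR-450a-5p (0.57 ± 0.13), miR-542-5p (0.80 ± 0.18), miR-542-3p (1.01 ± 0.24) and miR-503-5p (1.23 ± 0.33), which are made from clustered genes, rose. The other tested arms of that cluster, miR-503-3p (0.52 ± 0.18, which passed in 6 alternatives) and miR-322-3p (0.30 ± 0.14), did not pass. miR-181c-5p (0.55 ± 0.14), miR-181c-3p (0.61 ± 0.14) and miR-181d-5p (0.68 ± 0.14) rose. miR-489-3p (-0.87 ± 0.16) and miR-653-5p (-0.99 ± 0.16), both from an intron of Calcr, fell, and miR-653-3p (-0.72 ± 0.36) did not pass. Of 3 tested names that are not in the fixed Dlk1-Dio3 list but lie within its span on GRCr8, miR-409b and miR-3578 (-1.53 ± 0.34) fell, and miR-3543 (0.35 ± 0.25) did not pass. Mean scaled CPM of miR-3543 were 5.13, 3.99 and 4.26 on 0.01%, 0.4% and 4% NaCl. A member of the list had 5.1, 4.01 and 4.22, so the 2 names may hold the same reads.

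A hypothesis is that changes follow shared transcription units. Outside the Dlk1-Dio3 list and its span, 237 pairs of miRNAs with genes within 10 kb of each other differed by a mean of 0.217 in log2 fold change, against 0.54 after shuffling (permutation p = 1e-04, the smallest that 10000 shuffles can give). With that cluster included the values were 0.284 and 0.8. The shuffles moved single names, although arms of 1 hairpin and members of large clusters each enter many pairs. The permutation p therefore overstates the evidence. Regulation at transcription would give such closeness, but near-identical neighbours that share reads would look the same. Some pairs said above to share reads are among the neighbours and were not separated.

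Other splits of the same libraries bear on whether the counts arise by chance. For 87 calls between 0.01% and 0.4% NaCl, 1 of 100 splits, the real one, gave as many, and the highest other gave 45. For the 38 higher and 68 lower names between 0.01% and 4% it was 1 of 100 with a highest other of 2. For 85 with any diet difference it was 1 of 100 with 26, and for 81 with a trend 1 of 100 with 13. No other sampled split of single libraries reached any of these counts. The splits treat libraries as independent, so they cannot exclude chance differences between pools, which libraries of a diet may share. Between 4% and 0.4% this test says nothing, since any split gives at least 0 calls: 100 of 100 did, and the highest other gave 5. For the 11 list tests called by camera with a preset correlation, 50 of 100 splits gave at least 11 and the highest other gave 24, so chance cannot be excluded for that number, and the camera calls in themselves are weak evidence.

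The 0.01% NaCl libraries differed from both other diets. They were also sequenced more deeply, but with every library thinned to the smallest total the calls against 0.4% NaCl had a median of 83.5 in 10 draws. Leaving out the 5 most abundant names gave 92 calls. Without the 3 libraries rich in other-species names 78 of the 87 calls passed again, and the median size of the tested calls was 1.15 against 1.16. Of the tested calls 100% kept their sign. That refit reuses the other libraries in which these names were called, so a kept sign was likely beforehand. These tables argue against depth, dominant miRNAs and those 3 libraries as the whole cause. An effect of the diet stays open as a hypothesis, as do differences in processing that follow the diets, which the labels do not record.

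Most Dlk1-Dio3 miRNAs were lower on 0.01% NaCl. Of 10000 random lists matched on abundance, 0% had a median as low as -1.42, which argues against a general loss of scarce miRNAs. The middle 95% of their medians ran from -0.297 to 0.218. The smooth muscle and fibroblast list had a median of 0.637, where a smaller share of those cells predicts a negative value. Its fry adjusted p of 0.036 was kept in 4 of 15 refits without 1 library, and was 0.0725 with library totals only. Several of its members have neighbouring genes and 2 share reads. The list may thus follow few genes, and it cannot decide on the share of those cells. Whether some reads were counted under several names cannot be told apart from shared regulation: 39.1% of member pairs kept a log2 ratio with an SD within counting error, between the bounds of 10% and most pairs set before the test. A first version of this test, with a chi-square p above 0.05 in place of that bound, gave 64.3% of pairs. Matched random names gave means of 6.07% and 21.6% in the same tests, so abundance does not account for the difference over the whole list. The 7 members with a mean of at least 50 reads gave 9.52% and 14.3%, and no matched names were drawn for them. Whether abundance makes the difference within the list was therefore not tested.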
